A study of Rattus norvegicus with 14 samples.

How the data were processed

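Glomeruli, the filtering tufts of the kidney, were sieved from the kidney cortex of male Dahl salt-sensitive rats (SS/JrHsdMcwiCrl), an inbred strain that becomes hypertensive on a salt-rich diet. Per the series design, one group of rats ate chow with 4% NaCl and the other chow with 0.4% NaCl for 21 days from 8 weeks of age. Per the labels' protocols, RNA was extracted with TRIzol and made into 3' tag libraries (Lexogen QuantSeq FWD), in which each transcript is read only near its 3' end, and sequenced on an Illumina NextSeq instrument. There were 14 libraries, 7 on each diet, and the diet of each library was taken from its title. The title also carries a sample number, from 9 to 24, with odd numbers on high salt and even numbers on normal salt. The labels do not say what the numbers record, nor whether each library came from a separate rat, so the p-values measure the spread between these libraries.

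The authors deposited raw counts per gene for 12934 rat Ensembl gene IDs, and no gene in this table had a mean below 3 counts over the 14 libraries. They also deposited the same counts divided by 1 factor per library, a normalized signal, together with the mean of each diet, the ratio or fold of the means, and its log2. Division of the raw by the normalized values gave 1 constant per library. Per the submitters' processing notes, DESeq2 1.18.1 in R 3.4.3 was used. The same notes name GRCm38, a mouse build, whereas the gene IDs in the files are rat IDs, so the build behind the counts is uncertain and no coordinates are given. The aligner, the counting program, the annotation release and any use of molecular identifiers are not given in the sources used here. Whether the counts are of reads or of molecules is therefore unknown.

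The files do not pair the Ensembl IDs with gene names, and the table of rat genes used here matched 0 of the 12934 IDs. No gene could be named. The 34 gene lists fixed before the data were examined (glomerular and tubular cell types, immune cells, matrix, vasoactive and metabolic pathways) could not be applied, and 0 lists were tested. The rule for named genes, also fixed before, was to name the 12 genes with the most positive and the 12 with the most negative fold among called genes with a symbol and a mean of at least 5 CPM, up to 4 members of each list, and a set of 20 glomerular and injury genes. It gave no names. The 4 IDs printed are the 2 higher and the 2 lower IDs with the smallest p, and were chosen after their values were seen.

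Differences between the diets were tested on the raw counts with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood F-test, TMM factors, filterByExpr, no covariate), as planned. The filter removed 1776 IDs and left 11158. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors and 95% intervals of log2 fold changes were derived from the F statistic and its degrees of freedom. Log2 CPM, counts scaled to the library total after TMM correction, were computed with a prior count of 2 for principal components. Single values per library were compared by two-sided exact permutation tests over the 3432 splits of 14 libraries into 7 and 7. Correlations across libraries were tested with 100000 permutations, or with all orders within a diet.

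The pipeline was tested on simulated data before it was applied. Counts were drawn at the means, dispersions and depths of these libraries with 200 changed genes, 50 each at 1.5-, 2-, 3- and 4-fold. There were 10 repeats of the comparison of the diets, with 11004 to 11065 genes tested. A 2-fold change was called in 65.6% ± 6.3 (SD over repeats) of those genes and a 4-fold change in 92.6% ± 4.1. A median of 7 genes without a change were also called per repeat, at most 13. Known changes were also put into the real libraries by thinning counts.

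Alternatives fixed before the data were examined were RLE and upper quartile factors, no filter and a stricter filter (5 CPM in 7 libraries), DESeq2 1.42.0, limma 3.58.1 (voom with quality weights, and limma-trend on log2 of the authors' normalized values plus 1), blocks of consecutive sample numbers, other thresholds, and leaving out each library. Fits with the sample number or 2 surrogate variables (sva 3.50.0), fits within ranges of the number, the tests of the whole profile, the comparison of the share of the 10 most abundant genes, and all tests on the sample number were added after the data were seen.

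Total counts ranged from 13797146 to 18151197 per library. No libraries were identical: over the 42 pairs of libraries on the same diet, the chi-square per degree of freedom of their counts lay between 19.7 and 423.72, where sampling noise alone gives about 1. No library was left out.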

Results

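Transcripts of isolated cortical glomeruli were counted in 14 libraries from Dahl salt-sensitive rats, 7 on a high salt diet (4% NaCl) and 7 on a normal salt diet (0.4% NaCl), each given for 21 days. The design asks which glomerular transcripts differ between rats of this strain on the high salt and on the normal salt diet. The libraries held 13797146 to 18151197 counts each. The mean total was 16117736 ± 1419960 counts (SD, n = 7) on high salt and 15146360 ± 1344789 counts (SD, n = 7) on normal salt, a difference of 971376 counts that was within the spread (exact permutation test, two-sided, p = 0.211). Of 12934 Ensembl gene IDs in the table, 11158 passed the filter on low counts and were tested. Genes are given by Ensembl ID, since the files do not pair IDs with names.

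No glomerular gene passed the test for a rise or a fall on the high salt diet. Of the 11158 genes, 0 were higher and 0 lower at an adjusted p below 0.05 by edgeR's quasi-likelihood test, and the smallest adjusted p was 0.9997. The count of called genes was also 0 with DESeq2, with limma voom and with limma-trend. At an unadjusted p below 0.05 edgeR listed 202 genes (1.8% of those tested), fewer than the 558 that evenly spread p-values would give, and DESeq2 listed 343 of 12934. The shortfall was not seen in every fit: limma voom with quality weights listed 566 genes, edgeR with blocks of consecutive sample numbers 665, and edgeR without normal salt replicate 22 listed 597. Of the 202 genes, 36.6% were higher on high salt. When each library was left out in turn, this share ran from 24.9% without high salt replicate 9 to 54% without high salt replicate 21. The median log2 fold change over all genes was -0.002 and the median absolute log2 fold change was 0.108.

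**Figure D1:**
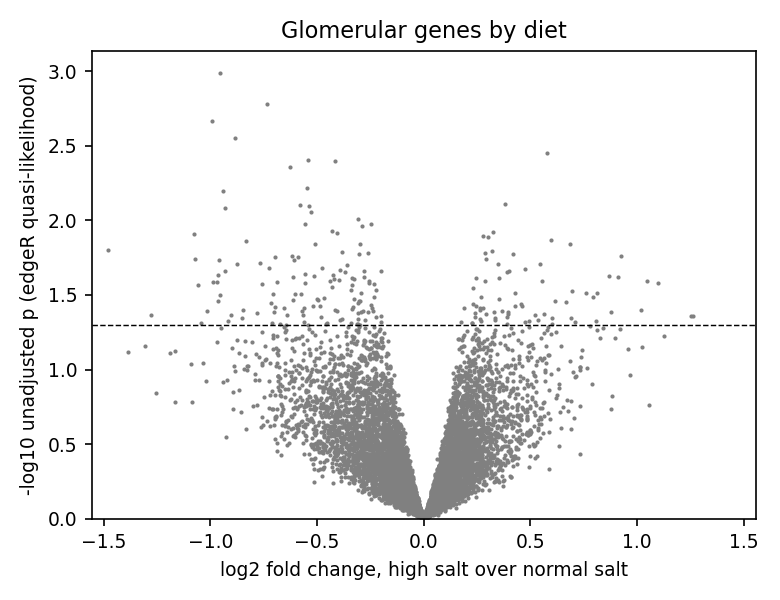
Each point is 1 of 11158 genes. The horizontal axis is the log2 fold change of 7 high salt over 7 normal salt libraries, the vertical axis is minus log10 of the unadjusted edgeR p, and the dashed line marks the unadjusted threshold of 0.05. The 202 genes above the line lie on both sides of 0, and none passed the adjusted threshold.

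For most genes the data limited how large a diet difference could be. The 95% interval of the fold lay inside a 2-fold change in either direction for 9719 of the 11158 genes (87.1%). It lay inside a 1.5-fold change for 6637 genes (59.5%). Among the 6765 genes with a mean of at least 10 CPM, 97.8% had an interval inside 2-fold and 81.9% inside 1.5-fold. The median standard error of the log2 fold change was 0.181 over all genes and 0.142 over these more abundant genes. Known changes were put into the counts of 200 genes of the real libraries at once, 50 genes each at 1.5-, 2-, 3- and 4-fold. Of genes with a 2-fold change, 62.6% ± 7.0 (SD over 10 repeats) were called. The same test called 25.6% ± 5.2 of genes with a 1.5-fold change and 88.4% ± 2.3 of genes with a 4-fold change. At 1.5-fold the share was 31.6% ± 6.1 with the sample number as a covariate and 41% ± 8.8 with blocks of consecutive sample numbers. Smaller differences were not detectable for many genes in these libraries. The shares called hold for 200 genes changed together, which makes the adjusted threshold easier to pass. They were not measured for fewer changed genes, nor for 2-fold changes without the 3- and 4-fold changes beside them.

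The 2 higher and the 2 lower genes with the smallest p values, chosen after the values were seen, differed by less than 2-fold. ENSRNOG00000010843 had 1.30 ± 0.30 CPM on high salt and 2.52 ± 0.73 CPM on normal salt (SD, n = 7 each), a log2 fold change of -0.96 ± 0.24 (SE; edgeR, unadjusted p = 0.00103, adjusted p = 0.9997). It was counted between 17 and 59 times per library. ENSRNOG00000045560 had 12.3 ± 3.0 CPM on high salt and 20.5 ± 6.03 CPM on normal salt, a log2 fold change of -0.73 ± 0.20 (SE; edgeR, unadjusted p = 0.00166). Both lay below the normal salt median in 7 of 7 high salt libraries. ENSRNOG00000029912 had 8.41 ± 1.80 CPM on high salt and 5.64 ± 1.11 CPM on normal salt, a log2 fold change of 0.58 ± 0.17 (SE; edgeR, unadjusted p = 0.00354). ENSRNOG00000008215 had 37.1 ± 4.36 CPM on high salt and 28.5 ± 5.87 CPM on normal salt, a log2 fold change of 0.38 ± 0.12 (SE; edgeR, unadjusted p = 0.00776). These 2 genes lay above the normal salt median in 7 of 7 high salt libraries. The adjusted p of each of the 4 genes was 0.9997, so none of these differences passed the threshold.

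In the authors' deposited table, the means of the diets differed at least 2-fold in 232 of 12934 genes, 78 higher and 154 lower on high salt. The log2 fold changes in the authors' deposited table ran from -2.33 to 2.71. Of these 232 genes, 26 had enough counts to be tested here and 0 were called by edgeR. For 155 of the 232 genes in the authors' deposited table (66.8%), leaving out 1 of the 14 libraries brought the fold of the means below 2. The genes were selected for passing 2-fold and any of the 14 omissions counted. A gene just above 2 falls below it readily, and no reference share was computed.

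A few very abundant genes took a large and variable part of the counts in both diets. The 10 most abundant genes held 47.5% ± 11.3 of all counts on high salt and 45.1% ± 5.2 on normal salt (SD, n = 7 each), a difference of 2.45 percentage points that was within the spread (exact permutation test, two-sided, p = 0.618). Their share ran from 30.79% in high salt replicate 21 to 64.85% in high salt replicate 15, and without replicate 15 the difference was -0.435 points. The most abundant gene alone held 13.2% ± 3.71 of counts on high salt and 12.2% ± 1.58 on normal salt (exact permutation p = 0.526). Outside these 10 genes, 8375871 ± 1490234 counts remained per high salt library and 8310009 ± 1022354 per normal salt library (SD, n = 7 each). The lowest was 5724641 counts, in high salt replicate 15. A high salt library had counts for 12731 ± 119 genes and a normal salt library for 12808 ± 24.9 genes (exact permutation p = 0.0897). Of 9 such measures compared between the diets, including 4 principal components, none passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.795, exact permutation tests).

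**Figure D2:**
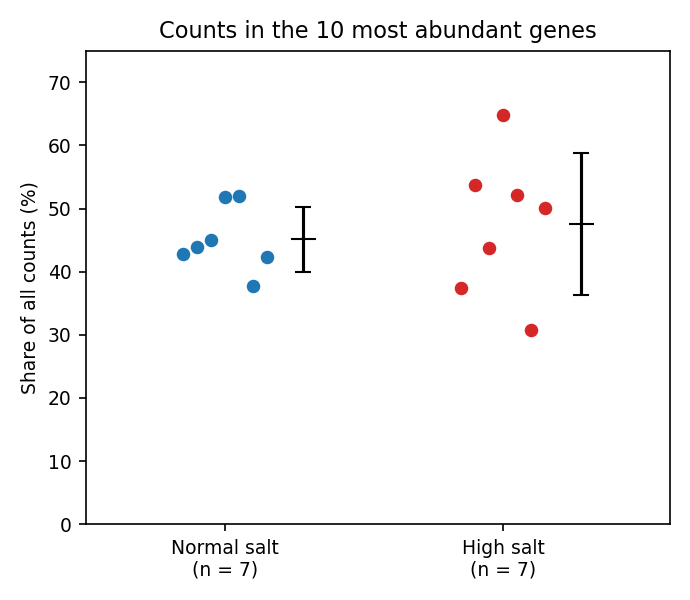
Share of all counts, in percent, held by the 10 most abundant genes in each library, with the 7 libraries of each diet as points in order of sample number and the mean ± SD beside them. The diets overlap, at 45.1% ± 5.2 on normal salt and 47.5% ± 11.3 on high salt, and the highest point is high salt replicate 15 at 64.85%.

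The libraries did not separate by diet in their whole expression profile. Diet accounted for 5.63% of the variance of log2 CPM over the 11158 genes, and random splits of the libraries into 7 and 7 accounted for a median of 7.05% (exact permutation test, p = 0.749). When the diets were swapped only within consecutive sample numbers, the median was 5.27% (exact permutation test over 128 arrangements, p = 0.359). Libraries were instead ordered by the sample number in their labels. The first principal component, with 30.4% of the variance, correlated with sample number over 14 libraries (Pearson r = 0.82, permutation p = 0.00039, Benjamini-Hochberg adjusted p = 0.00156 over 4 components, and Spearman rho = 0.80, permutation p = 0.00099, adjusted p = 0.00396). Without numbers 23 and 24, the 2 farthest from the median number, r was 0.87 (permutation p = 0.00019). The order was present within each diet, with r = 0.86 on normal salt (n = 7, exact permutation p = 0.0113) and r = 0.86 on high salt (n = 7, exact permutation p = 0.0157). The numbers alternate between the diets, and the mean number differed between them by 1.

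**Figure D3:**
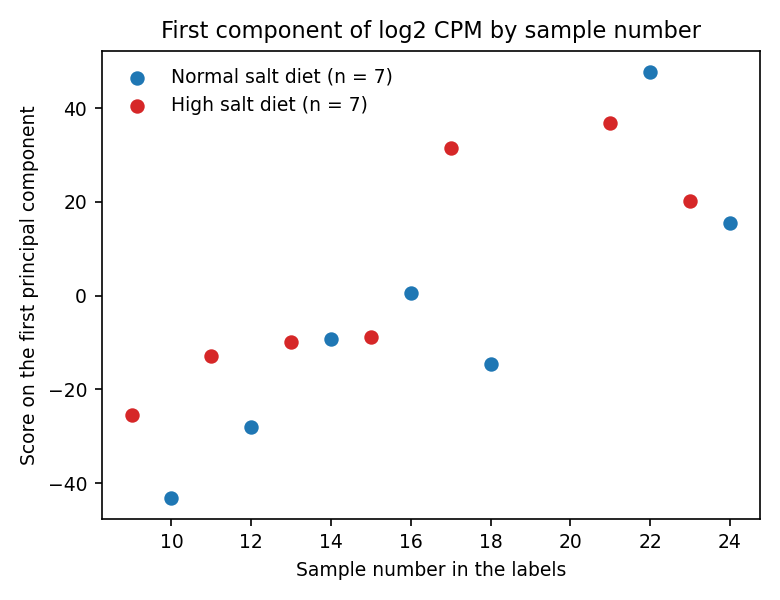
Score of each library on the first principal component of log2 CPM (30.4% of the variance) against the sample number in the labels, with the 7 normal salt libraries in blue and the 7 high salt libraries in red. Scores rise with the number in both diets (r = 0.82 over all 14) and the colours overlap.

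The diet comparison was therefore repeated within ranges of the sample number and with the number in the model. Numbers 9 to 16, with 4 libraries per diet, gave 0 called genes and 375 of 11231 at an unadjusted p below 0.05 by edgeR. Numbers 17 to 24, with 3 libraries per diet, gave 0 called genes and 153 of 11244. With sample number as a covariate, edgeR called 0 genes and listed 468 at an unadjusted p below 0.05. No gene passed the test for a diet effect that changed with sample number (0 called and 213 at an unadjusted p below 0.05, edgeR interaction term). How large a change this term could detect was not estimated.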

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

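Among 10 quantities tested in each diet group of 7 libraries, 1 of 20 groups held a library far from the others, and chance flags about 1 in 20 groups. In normal salt replicate 22, ENSRNOG00000008215 stood at 40.7 CPM, while the other 6 normal salt libraries lay between 23.1 and 30.37 CPM and the high salt libraries between 33.56 and 44.61 CPM.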

How the results depend on the processing

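The diet comparison gave 0 called genes under every alternative run: RLE and upper quartile factors, no filter and the stricter filter, DESeq2, limma voom with quality weights, limma-trend, blocks of consecutive sample numbers, adjusted p below 0.1 or 0.01, an added fold threshold, and, added after seeing the data, the sample number, its 2 ranges or 2 surrogate variables as covariates. Leaving out each library in turn also gave 0. The number of genes at an unadjusted p below 0.05 moved more, from 202 in the planned fit to 566 with limma voom and 665 with blocks of consecutive numbers (lowest adjusted p = 0.6023). Without single libraries it ran from 131 to 597, the highest without normal salt replicate 22. The diets share no sample number and the labels name no pairs, so the only paired fit was the one on consecutive numbers. Consecutive libraries deviated together from their diet means, with a mean correlation of 0.278 over the 7 pairs (exact p = 0.00536, one-sided, over 5040 matchings of the libraries). The correlation was over 0.1 in 6 of the 7 pairs, the exception being 17 with 18 at -0.10, and 4 of 7 high salt libraries matched their neighbour best. The trend with sample number was not removed, so these correlations cannot tell libraries handled as pairs from that trend. The share of the 10 most abundant genes differed between diets by -0.435 to 5.24 points over the libraries left out in turn and reversed only without high salt replicate 15. The difference in total counts ran from 632465 to 1353506 counts over the same omissions. The log2 fold changes of the 4 printed genes kept their sign in every fit that tested them, which is no independent support, since the genes were chosen on these libraries. Planned tests of gene lists, the proximal tubule covariate and totals without mitochondrial genes were not run, since no gene could be named. The 1776 genes removed by the filter were not tested in the planned fit. All were tested in the fits without it, and some when the filter was applied again to fewer libraries. Among the genes kept, with 200 changed together at 1.5- to 4-fold, 25.6% of known 1.5-fold changes were called in the planned fit. The share was 31.6% with the number as a covariate and 41% in blocks of consecutive numbers. The part of depth in this limit was not tested.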

Other observations

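The fit in blocks of consecutive sample numbers was planned. The other tests on sample number, and those of splits and of the whole profile, were chosen after the data were seen. The expectations for the shuffles, depth, abundant genes, known changes, the comparison of number ranges and the profile test with labels swapped within consecutive numbers were written before those results were seen. The expectations for diet as a cause of the order, for the splits and for spread tied to the number were written after.

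Expression of many glomerular genes followed the sample number. With diet in the model, edgeR called 1418 genes for a linear trend with the number, 778 higher and 640 lower at higher numbers, against 0 for diet. From number 9 to number 24 the fitted change of these genes had a median of 0.96 on the log2 scale (quartiles 0.73 and 1.38), and 661 of them changed by more than 1. The number accounted for 22.15% of the variance of log2 CPM, against a median of 7.13% when the numbers were shuffled (permutation p = 7e-04). The count depended on single libraries: it was 451 without normal salt replicate 22, 513 without normal salt replicate 10, 547 without high salt replicate 9, 762 without normal salt replicate 12 and 926 without high salt replicate 21, and it reached 2118 without high salt replicate 23. Of the genes called without normal salt replicate 22, 446 were among the 1418. A contrast of numbers 9 to 16 with 17 to 24 called 0 genes at 0.05 and 1361 at 0.1.

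Technical explanations for this order were weighed. Chance was made unlikely by the shuffles, since only 1 of 100 orders, the real one, called as many genes, and the highest of the others called 1. The shuffles do not count that the sample number was chosen after the data were seen, so chance is not excluded. Depth was partly tied to the number, though not at p below 0.05. The correlation was r = 0.469 for total counts (permutation p = 0.0899) and r = 0.453 outside the 10 most abundant genes (permutation p = 0.103). After each library was thinned to the same depth outside these 10 genes, 1238 of the 1418 genes were still called. This argues against sequencing depth as the whole cause. With the share of the 10 most abundant genes as a covariate, 1384 were still called. The share hardly followed the number (Pearson r = -0.126, permutation p = 0.669), so this covariate could remove few calls. It is the weak correlation, more than the count, that argues against these genes as the whole cause. Diet cannot give an order within a diet, and the lower of the 2 correlations there was 0.86. A day or batch of dissection, sieving or library preparation, a litter, or a different share of tubule fragments may each follow the number, and these stay open because the labels do not say what the number records and no cell type marker could be named.

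The absence of called genes between the diets was weighed in the same way. With 0 genes called for diet, 100 of 100 splits of the libraries necessarily call as many, so the count of splits decides nothing here; the highest of the other splits called 12. At an unadjusted p below 0.05, 79 of the 99 other splits listed at least the 202 genes of the diets, and the most listed was 2068. The 7 lowest against the 7 highest sample numbers listed 3187 and called 671. A contrast of numbers 9 to 16 with 17 to 24, which differs in the side of number 16, listed 2963 but called 0. The called count thus depends on the cut, which was chosen after the trend was seen. The listed counts point to a structure of the libraries along the number. That this structure hides a mix of diet effects like the one put in, 1.5- to 4-fold in 200 genes at once, is argued against. With the number as a covariate or in blocks 0 genes were called, where 67.6% and 70% of known 2-fold changes were called. The blocked fit also called a median of 7 genes into which no change had been put, the covariate and planned fits 0. On simulated libraries the planned fit too called a median of 7 such genes. In these tests 200 genes were changed together, 50 each at 1.5-, 2-, 3- and 4-fold. The larger changes make the adjusted threshold easier to pass for the 2-fold genes. Diet effects of 2-fold in few genes, or in many genes without larger changes beside them, stay open. A depth too low to call 2-fold changes within the mix put in is argued against. In the planned fit 62.6% of those 2-fold changes were called. Depth itself was not varied, so its part in the changes that were missed was not tested. Small changes spread over many genes stay open. The diet differences of numbers 9 to 16 and 17 to 24, which share no library, correlated across genes at r = -0.026 (rho = 0.019, genes are not independent replicates). This r lay within the range of 1400 relabellings (exact p = 0.563, one-sided). The profile test with labels swapped within consecutive numbers gave an exact p of 0.359. By the expectation written before, a correlation of 0 or below with a profile p of 0.05 or more would count against such changes. Both were met, but r lay within the range of the relabellings, so no verdict was drawn, a departure from that expectation.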
